A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

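Total RNA from 2 strains of the yeast Saccharomyces cerevisiae was measured on 8 two-colour Agilent arrays, 1 array per strain and time. Per the labels, the Cy5 channel held the sample and the Cy3 channel a common reference, RNA of strain DBY12021 from a phosphate-limited chemostat, on every array, so no dye was swapped and each ratio is sample over reference. Per the labels' protocols, cells grew at 30 °C with urea at 1 g/L as the nitrogen source, received 1 µM beta-estradiol at 0 min and were sampled at 0, 30, 90 and 180 min, and 415 ng of total RNA was labelled. The series' design text names GEV and sets ARO80 under the GAL1 promoter against a control strain, and it can be read as GEV in one strain or in both. GEV is a fusion of the Gal4 DNA-binding domain, the oestrogen receptor and the VP16 activation domain. The labels give GEV to the ARO80 strain and no activator to the control strain, whereas the names attached to the deposited arrays carry ZEV for the ARO80 strain and GEV for the control strain. Groups were taken from the labels, which do not name the carbon source.

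The deposited scanner files hold spot intensity on a linear scale for both channels, with the local background, made by Agilent Feature Extraction 9.5.3.1 per the file headers. They also hold a log10 ratio of Cy5 over Cy3 which, per the file headers, followed Agilent's background subtraction, spatial detrending and dye normalization. The deposited series value table holds log2 ratios of the same spots: each value was within 0.0005 of the scanner file's ratio put on the log2 scale, so its direction and scale are settled, and its column medians lay between 0.001 and 0.045. It lists 14810 of 15208 non-control spots, and what was left out of it is not given in the sources used here. Median signals were 4691 to 7036 for Cy5 and 1543 to 1669 for Cy3, 93.3% to 98.0% of probes were well above background in Cy5, and 0 to 3 spots per array were saturated. The number of arrays limits the precision.

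Mean foreground and median background signals were corrected by normexp with an offset of 50 and normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Spots marked as non-uniform or population outliers (250 to 301 per array) were left out. The 2 or 3 spots of a probe were averaged, with a median SD over spots of 0.030 to 0.044 on the log2 scale. Each gene had 1 probe. Of 6256 probes, 6110 had Cy5 well above background on at least 3 of the 8 arrays, and 6108 had a value on every array. Gene names came from a RefSeq table of assembly R64 matched by locus tag, which held 5756 of the probes. The other 500 kept the name in the files. No coordinates are given because the array design used an older build.

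The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. A limma model with sampling time, strain, and strain by after-treatment was fitted to all 8 arrays, which leaves 2 residual degrees of freedom, moderated across genes (prior 2.23). Its contrasts were the mean strain difference over 30, 90 and 180 min, that mean minus the difference at 0 min, and the mean of the later times minus 0 min in each strain. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. No replicate cultures were measured: the spread is how the strain difference varied over the 3 later times, the lone 0 min arrays are assumed to vary alike, and p-values describe these 2 time courses. At single times sizes are given without a test. All arrays lie on 1 slide, the control strain in one column and the ARO80 strain in the other, so strain and slide column cannot be told apart. Treatment and time in culture cannot be told apart either.

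Camera with a preset correlation of 0.01 was run on 34 gene lists with at least 3 measured members, and again with the correlation estimated. The estimate rests on the model's 2 residual degrees of freedom. A list that does not pass with it is therefore not shown to be unchanged. At each time a list's median was also ranked among 10000 random lists matched on brightness. Named genes were ARO80, ARO9, ARO10, ESBP6 and 6 GAL genes, then the 10 highest and 10 lowest genes past the threshold with 1 sign at all 3 later times, filled by size where fewer passed, then up to 4 members of each list described. Other genes are said to have been chosen after their values were seen. Where a gene was not well above background on any array of a group, no fold is given.

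The model was tested on simulated arrays of 6108 genes for the strain difference after treatment, with 200 genes changed: it recovered 6% of 2-fold, 64% of 4-fold, 94% of 16-fold and 98% of 64-fold changes, with 10 false calls. The simulated noise was independent between genes and the simulated strain difference constant over time. Neither holds in the data, so these figures may not carry over to them. Alternatives covered background correction, the source of the ratios, scaling, channel, filter, flags, the variance model, the time block, each later time left out and a fold threshold. A model that takes the spread from the 4 control arrays, with the control times as replicates of 1 mean, was added after seeing the data. It is counted among the alternatives for the difference after treatment and its change, so ranges of values and adjusted p over them include it. The fold threshold, Aquantile scaling and the 6 later arrays alone repeat the main contrast, so they add little to these ranges.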

Results

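RNA abundance was followed in 2 yeast strains of S288C HAP1+ background after beta-estradiol, in a control strain and in a strain with ARO80 under the GAL1 promoter, to ask which transcripts change when ARO80 is overexpressed. ARO80 encodes the transcription factor that activates genes of aromatic amino acid breakdown. Each strain was measured on 1 array at each of 0, 30, 90 and 180 min, so no value has a replicate. The strains lie in different columns of the slide, and strain and column cannot be told apart. All values are log2 ratios to the common reference, or log2 differences between them. Across genes, the control arrays correlated with each other at r = 0.91 to 0.96. The ARO80 arrays correlated with the control array of 0 min at 0.70 at 0 min, 0.46 at 30 min, -0.11 at 90 min and -0.04 at 180 min.

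The induced gene was examined first. In the ARO80 strain the ARO80 log2 ratio was -0.98 at 0 min, 6.87 at 30 min, 7.55 at 90 min and 8.10 at 180 min. In the control strain it was 1.51, 0.43, 0.87 and 0.43. Before beta-estradiol ARO80 RNA was therefore lower in the ARO80 strain, by -2.48. After treatment it was higher by 6.93 (SE 0.30; limma adjusted p = 0.011), a 122-fold difference with the same sign at all 3 times. The change of the strain difference from 0 min was 9.41 and did not pass in limma (adjusted p = 0.36). From Cy5 alone the ARO80 difference after treatment was 6.11, or 68.9-fold, because the reference signal was lower at this probe on the later ARO80 arrays. Without the 90 min or the 180 min arrays the difference was 7.05 or 6.56, but its limma adjusted p was 0.16 or 0.090, and over 17 alternatives it ranged from 1.8e-05 to 0.16.

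**Figure D1:**
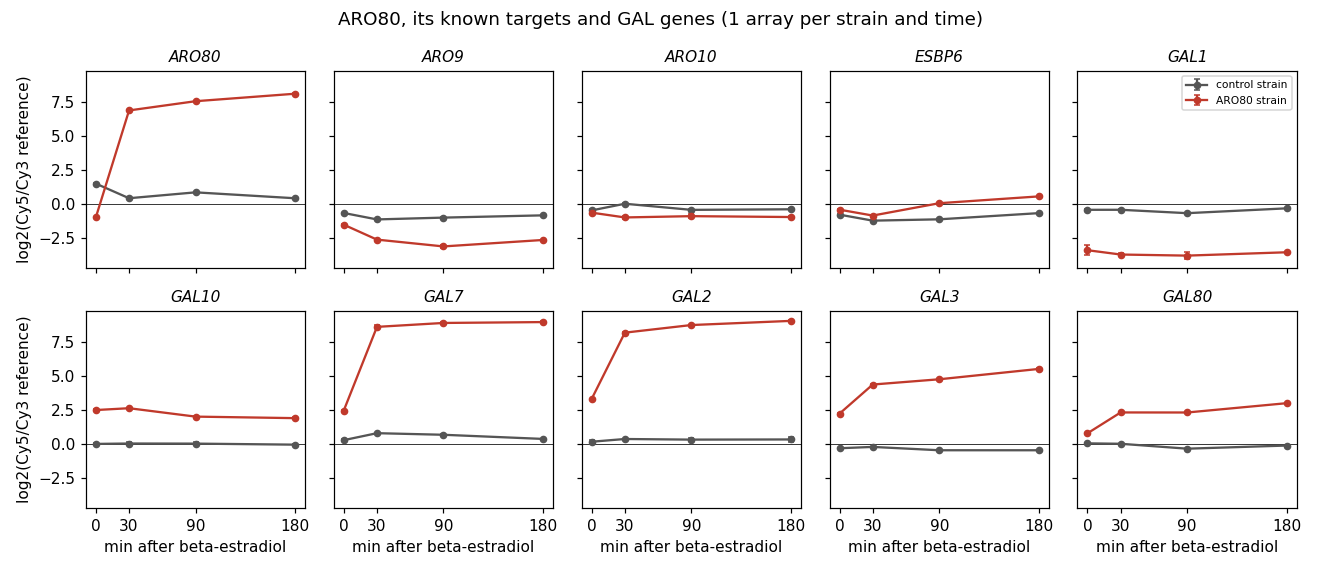
The log2 ratio of Cy5 to the Cy3 reference is plotted against min after beta-estradiol for 10 genes, grey for the control strain and red for the ARO80 strain, with points for single arrays and bars for the SD over the spots of a probe. ARO80, GAL7, GAL2, GAL3 and GAL80 stood higher at 30 min than at 0 min in the ARO80 strain, whereas ARO9 was -1.50 at 0 min and -2.60 at 30 min.

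The known targets of Aro80 were not higher as a group. ARO9, an aromatic aminotransferase, was lower in the ARO80 strain after treatment by -1.80 (SE 0.20; limma adjusted p = 0.049), and over 17 alternatives the limma adjusted p ranged from 0.00012 to 0.37, with no call in 3 of them. The change of the ARO9 strain difference from 0 min was -0.94 and did not pass in limma (adjusted p = 0.99). By size, -0.94 against -1.80, part of the difference was present before treatment. ARO10, a phenylpyruvate decarboxylase, differed by -0.68 (adjusted p = 0.093), and ESBP6 by 0.93 (adjusted p = 0.086), and neither passed. ARO10 ranged from -1.48 to -0.52 and passed in 2 of 15 alternatives, and ESBP6 passed in 2 of 17. Of the 4 genes of the list, ARO80 itself included, 1 was higher, 1 lower and 2 did not pass. Adjusted over the list alone, 2 were higher and 2 lower. The list did not pass in camera (adjusted p = 0.89).

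Targets of Gal4, whose DNA-binding domain GEV carries, were higher in the ARO80 strain after treatment. Of 12 measured, 8 were higher, 1 was lower and 3 did not pass, and adjusted over the list alone 11 were higher and 1 lower. GAL2, the galactose permease, was higher by 8.30 (SE 0.24), GAL7, a galactose-1-phosphate uridylyltransferase, by 8.19 (SE 0.22), and GCY1 by 6.05 (SE 0.32), with limma adjusted p of 0.0064, 0.0064 and 0.013. GAL3 was higher by 5.25, GAL80 by 2.69 and GAL10 by 2.17. From 0 min the strain difference changed by 2.71 at GAL3, 1.95 at GAL80 and -0.31 at GAL10, changes that did not pass. GAL10 was therefore already higher in the ARO80 strain before treatment. From Cy5 alone GAL2 differed by 10.86, GAL3 by 6.37, GAL10 by 3.06 and GCY1 by 5.05, and GAL7 was 512-fold rather than 291-fold higher. GAL1, the galactokinase, was lower by -3.20 (SE 0.16; limma adjusted p = 0.013), and was well above background on 1 of the 3 later ARO80 arrays and not at 0 min. The GAL1 strain difference changed from 0 min by only -0.24, which did not pass. By size it was therefore largely present before treatment. Over the alternatives GAL1 ranged from -4.87, from the Feature Extraction ratio, to -3.17. The list passed in camera (adjusted p = 4.9e-07; adjusted p = 0.79 with an estimated correlation). Strain differences were present before treatment: at 0 min the list's median was 0.97, against 2.79, 3.71 and 3.67 at 30, 90 and 180 min.

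Over all genes, 86 of 6108 differed between the strains after treatment in limma at adjusted p under 0.05, 61 higher and 25 lower in the ARO80 strain, and 2341 had an unadjusted p under 0.05 where 305 would by chance. In limma no gene passed without the 90 min or the 180 min arrays, where 766 and 1119 had an unadjusted p under 0.05, and 1899 passed without the 30 min arrays. Among the highest were LEU2 at 6.35, an enzyme of leucine synthesis, PGM2 at 5.93 (4.96 from Cy5 alone), a phosphoglucomutase, YTP1 at 5.77, ZRT1 at 5.69, the high-affinity zinc transporter, and GAC1 at 5.10. By size alone, 37 genes were at least 4-fold higher and 20 at least 4-fold lower in the ARO80 strain at each of the 4 times, 0 min included. LEU2, PGM2, YTP1, ZRT1 and GAC1 were among the higher. Without the 90 min arrays PGM2 was 5.07, and without the 180 min arrays LEU2 was 6.95, both no longer past the threshold. LEU2 was at -6.97 to -7.20 in the control strain at all times and at 0.40 in the ARO80 strain at 0 min. URA3 was higher by 2.93 (limma adjusted p = 0.027), so both marker genes differed between the strains throughout.

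Amino acid permeases were among the genes lower in the ARO80 strain. Of 16 genes of the permease list, 7 were lower, 1 was higher and 8 did not pass, and adjusted over the list alone 10 were lower and 4 higher. AGP1 was lower by -5.85 (SE 0.18; limma adjusted p = 0.0064), BAP3 by -5.60, BAP2 by -4.60, GNP1 by -4.51, TAT1 by -4.05, DIP5 by -3.90 and TAT2 by -3.55. All 7 were already at least 4-fold lower at 0 min. Over the alternatives DIP5 ranged from -6.97 to -2.80, BAP3 from -7.26 to -5.47, BAP2 from -5.45 to -4.50, TAT1 from -4.74 to -3.87 and TAT2 from -4.74 to -3.36, the lowest from Cy5 alone in each case. The list passed in camera (adjusted p = 0.0010; adjusted p = 0.79 with an estimated correlation), and its median was already -2.72 at 0 min. SNZ1, of vitamin B6 synthesis, was lower by -5.59 (-4.96 from Cy5 alone) and HXT3, a low-affinity glucose transporter, by -4.75, against -4.80 and -3.67 at 0 min. Of the 4 alpha-specific genes, MF(ALPHA)2 at -4.82 and SAG1 at -2.80 were lower and STE3 at -2.73 and MF(ALPHA)1 at -2.63 did not pass, and the median of the list was -1.17 at 0 min and -4.37 at 180 min. MF(ALPHA)2 ranged from -6.54 to -4.25 over the alternatives, the lowest from the Feature Extraction ratio. The list passed in camera (adjusted p = 0.0011; adjusted p = 0.79 with an estimated correlation). Of 6 a-specific genes 0 passed, with a median of 0.36 (camera adjusted p = 0.38).

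Ribosome, stress, respiration and Gcn4 lists passed in camera with the preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.79 for each). Few or no members passed over all genes. Of 138 cytosolic ribosomal protein genes 0 passed over all genes and 133 were lower adjusted over the list alone, with a median of -2.15. Their median strain difference was -0.36 at 0 min, -0.51 at 30 min, -2.94 at 90 min and -3.09 at 180 min. Of 58 ribosome biogenesis genes 0 passed and 55 were lower over the list alone, with a median of -1.92. Their median was already -1.44 at 0 min, where 48 were at least 2-fold lower, and was -0.90, -2.92 and -1.91 at 30, 90 and 180 min. Of 37 genes induced in the environmental stress response 3 were higher, 34 did not pass and 35 were higher over the list alone, with a median of 2.96. The 3 were GCY1, PGM2 and GAC1, of which GCY1 and PGM2 are also in the Gal4 list. The median of the stress list was already 1.81 at 0 min, where 28 genes were at least 2-fold higher. It was 1.38, 4.29 and 3.66 at 30, 90 and 180 min. Of 34 respiratory chain genes 0 passed and 16 were higher over the list alone, with a median of 1.32. Of 40 Gcn4 targets 1 was lower and 16 were lower over the list alone, with a median of -1.24. At 0 min the median was 0.75 for the respiratory chain and -0.51 for the Gcn4 targets. In all, 14 of 34 lists passed in camera, 4 up and 10 down, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.79. That correlation comes from 2 residual degrees of freedom, which hold how the strain difference varied over the later times. It was 0.97 for ribosomal proteins, 0.91 for ribosome biogenesis, 0.09 for Gal4 targets and -0.03 for permeases. With it 0 lists passed in any contrast. Whether this reflects the few degrees of freedom or a lack of change beyond the spread cannot be told from these arrays. The calls rest on the preset correlation of 0.01, which takes the genes of a list as nearly independent. The estimates for ribosomal proteins and ribosome biogenesis lie far above that value. In each contrast the lists that passed therefore describe these time courses, and do not show what other cultures of the strains would give.

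**Figure D2:**
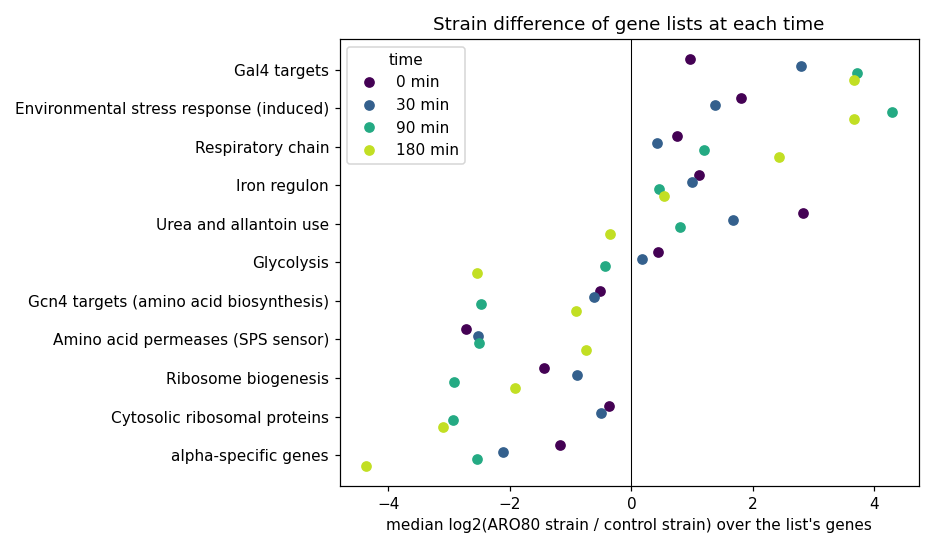
The median log2 ratio of the ARO80 strain to the control strain is plotted for 11 gene lists, 1 point per time and list. The ribosomal protein median was -0.36 at 0 min and -3.09 at 180 min, and the urea and allantoin list went from 2.82 to -0.35.

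Whether the strain difference changed from before treatment was asked with the second contrast, and 0 genes passed in limma (76 at an unadjusted p under 0.05 against 305 by chance, smallest adjusted p = 0.36). The spread is how the strain difference varied over the later times, so late change itself widens it. ARO80, the induced gene, did not pass either, so these 0 calls do not show that strain differences stayed unchanged. Among genes with 1 sign at all 3 later times, values that did not pass included ARO80 at 9.41, GAL7 at 6.03, GAL2 at 5.17 and GCY1 at 4.97, and on the lower side HXT2 at -3.70 and DAL4, the allantoin permease, at -3.64. Values at HXT6 (-3.18) and HXT7 (-3.72) are uncertain because these transporters are near-identical. In camera 19 of 34 lists passed, 4 up and 15 down, and with an estimated correlation 0 did (lowest adjusted p = 0.68). They include ribosomal proteins with a median of -1.78, the urea and allantoin list with -1.70, glycolysis with -1.52 and the Gal4 targets with 2.26. When the spread was taken from the 4 control arrays, a model added after seeing the data, 1536 genes passed, 855 higher and 681 lower. In that model the 4 control times are taken as replicates of 1 mean, so the same genes are the response of the ARO80 strain, whose 0 min side is 1 array.

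By size alone, 723 genes were at least 2-fold apart between the strains at 0 min, 625 at 30 min, 1998 at 90 min and 2123 at 180 min. Within the control strain 298, 45 and 89 genes were at least 2-fold from their 0 min value at 30, 90 and 180 min. Within the ARO80 strain these were 131, 1387 and 1775.

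**Figure D3:**
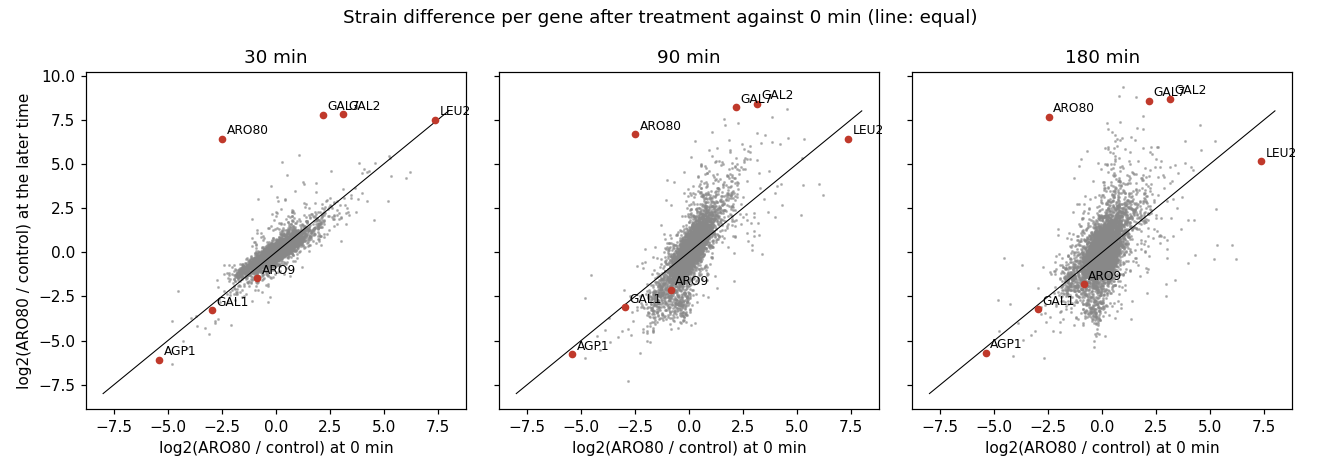
The log2 difference between ARO80 and control strain at 30, 90 and 180 min is plotted against that at 0 min, 1 point per gene, with the line of equal values. ARO80, GAL2 and GAL7 lie far above the line at each time, while AGP1 and GAL1 lie near it, and 625, 1998 and 2123 genes were at least 2-fold apart at the 3 times.

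In limma 0 genes passed for the response of the control strain to treatment (smallest adjusted p = 0.9998). At an unadjusted p under 0.05 there were 23, against 305 by chance. The spread in this model is how the strain difference varied over the later times, which includes the wide late change of the ARO80 strain. These 0 calls therefore do not show that the control strain did not respond. The fitted response was 0.33 at GAL7, 0.17 at GAL2, -0.07 at GAL3, -0.19 at GAL80 and -0.93 at ARO80. Among genes with 1 sign at all 3 later times, values that did not pass included HSP12 at 2.25, a stress protein, GSY1 at 1.78, a glycogen synthase, and PRM7 at -2.01. In camera 7 lists passed, of which ribosome biogenesis was down with a median of -0.71 and the stress response up with 0.67. None passed with an estimated correlation (lowest adjusted p = 0.99). In the ARO80 strain 0 genes passed in limma (234 at an unadjusted p under 0.05, smallest adjusted p = 0.077), and 443 did without the 30 min arrays. The same spread enters this contrast, so its 0 calls do not show that the ARO80 strain did not respond. For this response 18 lists passed in camera, 6 up and 12 down, and 0 did with an estimated correlation (lowest adjusted p = 0.75).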

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

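All tests of explanations in this part were chosen after the results were seen. Of 51 named genes, 11 moved one way from 0 min at each later time in the control strain and the opposite way at each later time in the ARO80 strain. Many of the 51 were named for having 1 sign at all 3 later times in a contrast, which favours such opposition. Its share over all genes was not counted, so the 11 are no result about the named genes. With 1 array per time, this opposition itself was not tested, and the model's test of the change did not pass for any of the 11. The change of the strain difference was 9.41 for ARO80, 3.43 for ADH6, 3.26 for PTR2, 1.95 for GAL80, -0.52 for ARO10, -1.30 for BAP2, -1.48 for BAP3, -2.95 for TPO2, -3.18 for HXT6, -3.23 for FRE2 and -3.72 for HXT7. The smallest control values behind these were near 0 for BAP3 (0.012), GAL80 (-0.031), ARO10 (0.041) and PTR2 (-0.043).

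Gal4 targets were higher after beta-estradiol in the ARO80 strain. If the control strain held an equally active estradiol-responsive Gal4-type activator, they should respond there too, but their median response in it was 0.014. A fixed difference between the slide columns would leave the ARO80 strain's own values still, but their median difference from 0 min was 2.61. A shift of the Cy3 reference would vanish from Cy5 alone, where the median strain difference was 3.32. The control may lack a working Gal4-type activator and then would not part effects of the activator from those of ARO80. Labels give GEV to the ARO80 strain and array names give it to the control. From 0 min the Gal4 list's median moved by 1.95, 2.79 and 2.86 at 30, 90 and 180 min in the ARO80 strain. In the control strain it moved by 0.085, -0.045 and 0.025. For these genes the values argue against GEV acting in the control strain alone, as the array names would have it. Whether the control strain carried any activator, and what else the ARO80 strain carried, stays open. LEU2 and URA3 RNA were at least 4-fold higher in the ARO80 strain at all 4 times, so the strains were not alike in these marker genes before treatment. How far they were otherwise isogenic stays open.

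The ARO80 strain moved far from its own start between 30 and 90 min. Noise of the late arrays is argued against by a correlation across genes of 0.67 between the change from 0 to 90 min and that from 30 to 180 min, which share no array, and a fixed column difference by 3.20 times as many genes 2-fold apart at 90 as at 30 min. A candidate explanation is exhaustion of glucose in that culture: from 30 to 180 min in the ARO80 strain the median difference of glycolysis genes was -2.67 and that of respiratory chain genes 1.70, against -0.09 and -0.13 in the control strain. The labels do not name the carbon source. An effect of ARO80, of the activator or of this culture's history stays open, and no array of the series parts them.

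The Cy3 signal, from the same reference on every array, differed where Cy5 was at least 32-fold brighter than on the control array. At 180 min 4 such genes had Cy3 over 2-fold lower, which Cy5 light read as Cy3 does not give, and 10 had it over 2-fold higher, which competition for the spot does not give. A mixture parted by the brightness of the reference was set to need medians beyond 0.3 in both directions, and missed it at 180 min, with -0.23 in the brighter-reference genes and 0.83 in the dimmer ones. At 90 min the medians were -0.36 and 0.55, and at 30 min, over 10 genes, -0.41 and 0.46, beyond 0.3 in both directions at both times. The origin of these shifts stays open, and no biological explanation was tested.

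With 3 arrays against 3 there are 10 splits of the 6 arrays after treatment, too few for a share under 0.05. The strain split called 86 genes, 1 of the 10 calling as many, and the highest of the others called 0. A split that mixes the strains puts the strain difference into the spread. Its 0 calls were therefore likely beforehand and are no measure of what noise alone would give. Only 4 of the 10, the strain split included, part the arrays of all 3 times, and the other 6 part 1 time and are not comparable in a model that blocks on time.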

How the results depend on the processing

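The model with the control arrays as the spread was chosen after seeing the data. Against 86 genes that differed after treatment, alternatives called 159 from the Feature Extraction ratio, 263 with trended robust eBayes, 1612 without the time block, 1899 without the 30 min arrays 0 without the 90 or the 180 min arrays, and 3824 with the control arrays as the spread. Leaving out any later time leaves 1 residual degree of freedom. The share higher was 70.9%, against 59.4% without the time block and 54.7% without the 30 min arrays. The change from 0 min called 4 without the time block and 1536 with the control spread. The ARO80 strain's response called 2 with offset 0, the Feature Extraction ratio, the series table or both channels above background, 3 with Cy5 alone or trended eBayes, 11 without the time block, 443 without the 30 min arrays and 1536 with the control spread. ARO80 after treatment was 7.05 and 6.56 without the 90 and 180 min arrays, no longer past the threshold. Its change was 9.41 without the time block and 8.48 with the control spread, now past it. Its response passed at 8.77 with offset 0, 8.81 in both deposited ratios, 7.75 with Cy5 alone, 8.80 without the 30 min arrays, and 8.48 with both channels above background, trended eBayes, no time block or the control spread. At 1.5-fold 1636, 1412, 3086 and 3319 genes were apart at the 4 times, and at 4-fold 140, 151, 907 and 818. The numbers of lists passing for the difference after treatment, its change and the control response were 0, 0 and 0 with an estimated correlation. That estimate rests on 2 residual degrees of freedom, so these counts do not show that the lists were unchanged. Among values that did not pass, the sign turned for the control response of GAL10 (0.0026 without background subtraction, 0.014 with outlier spots kept, 0.026 without the 180 min arrays) and GAL1 (0.055 without the 90 min arrays). For named genes, 1097 values under alternatives kept their direction and side of the threshold, 48 lost the call, 24 gained it and these 4 turned sign. Where a time was left out fewer arrays remain, and otherwise the cause was not tested. Aquantile scaling leaves ratios as they are by construction, so its equal counts are no evidence of stability, and the 6 arrays after treatment alone likewise repeat the same contrast. A fold threshold of 2 removed none of the 86 genes. The probe of highest Cy5 could not be tried because each gene has 1 probe. Probes not well above background limit what can be said of GAL1 in the ARO80 strain. The strains were compared within sampling times, and the fit without the time block is the unpaired one. No pairing by replicate number was possible because each group holds 1 array and the labels give no such numbers.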

Other observations

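The list of glucose-repressed carbon genes, the Zap1 list and FBP1, ICL1, MLS1 and GAL4 were chosen after the values were seen. Genes of growth on other carbon sources stood far apart late in the ARO80 strain: over 25 such genes the median strain difference was 0.57 at 0 min, 0.84 at 30 min, 2.70 at 90 min and 5.83 at 180 min, with 22 at least 2-fold higher at 180 min. At that time FBP1, fructose-1,6-bisphosphatase, had a log2 ratio of 7.79 in the ARO80 strain and -1.01 in the control strain, ICL1, isocitrate lyase, 7.91 and -0.93, and MLS1, malate synthase, 7.29 and -2.06. Over 18 genes of the Zap1 zinc regulon the median was 0.60 at 0 min and 1.28 at 180 min, and ZRT1 was higher by 5.25 before treatment.

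The urea and allantoin genes, on the study's nitrogen source, had a median strain difference of 2.82 at 0 min and -0.35 at 180 min.

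GAL4, the activator of the GAL genes, was well above background on 4 control arrays and on 0 of the 4 ARO80 arrays. In all 124 genes showed this pattern and 0 the opposite one, with a median strain difference of -0.08. Fewer probes were well above background on each ARO80 array (93.3% to 94.6%) than on each control array (97.3% to 98.0%), so the pattern of detection is not particular to GAL4. The mean strain difference at GAL4 was the lowest of the 124, however, at -1.32, with its ARO80 side not well above background.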
